A study of Mus musculus with 18 samples.

How the data were processed

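RNA of mouse bone marrow-derived mast cells was extracted with QIAGEN RNeasy kits and labelled with biotin for Illumina bead arrays, per the labels' protocols. The deposited files held, for 45281 probes on 18 arrays, an intensity before normalization and a detection p-value, per the file headers. The lowest intensity values lay near 71 to 79, so the deposited intensity still held the background. The authors also deposited a table on a log2 scale. Its 18 columns held the same sorted values to within 0.00077, with a median of 4.24 on every array, so it was quantile normalized; the authors' background method is not given in the file headers. In each array the rank order of the probes was that of the deposited intensity, with 0 inversions, and the highest rank correlation with another sample's column was 0.848.

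The intensity column of ST2KO IgE replicate 3 held 10012 of 45281 probes, with 35269 missing. For this array the normalized values were placed, by the rank order of the probes in the authors' table, onto the distribution shared by the 17 complete arrays. On the complete arrays 15911 to 17490 probes were detected, and on the incomplete array 3258 of 10012.

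The intensities were background corrected, quantile normalized and brought to a log2 scale with neqc of limma 3.58.1 in R 4.3.3, with an offset of 16 and negative controls inferred from the detection p-values. The result correlated with the authors' log2 values at 0.992 on the first array, across probes. Probes with a detection p under 0.05 on at least 3 of the complete arrays were kept, 19514 in all. Gene names came from the probe table and a table of the GRCm38.p6 assembly: 34885 probes carried 1 symbol, 18 several, and 10378 were not listed. Of the probes kept, 16637 carried 1 symbol, 7 several and 2870 none. Where a gene had more than 1 probe, as 4096 genes did, the probe with the highest mean level was taken, which left 10529 genes. The build of the array design is not named, so no coordinates are given.

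A limma model with 1 mean per group was fitted to all 18 arrays, which left 12 residual degrees of freedom. Spread was estimated with eBayes and an intensity trend, and p-values were adjusted by the Benjamini-Hochberg method within each of 8 comparisons at 0.05. The comparisons were each stimulus against no stimulation within each genotype, IL-33 against IgE in WT cells, ST2KO against WT in unstimulated cells, and the interactions of genotype with each stimulus. Each of 27 gene lists was tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and also with an estimated correlation and with fry. A fold change against a group with no detected array is given as at least the fold over the lowest detected level of that group's arrays, averaged over them. The comparisons, lists, named-gene rule and alternatives were fixed before the data were examined, except those said to be chosen after seeing the data.

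The genes named were Il1rl1; in each comparison the 10 largest rises and 8 largest falls among genes past the threshold whose groups did not overlap (6 and 6 for the genotype, ST2KO IL-33 and interaction comparisons, without the overlap condition for interactions), leaving out genes with clone or model names; up to 4 members with the smallest adjusted p and 2 abundant members that did not pass, for each list described, of which the text gives some; and a fixed set of 10 genes: Il13, Il6, Tnf, Il4, Ccl3, Mcpt8, Kit, Fcer1a, Gata2 and Hdc. A list was described where camera passed or at least 3 members did, and markers of other cell types always were.

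Residuals of arrays with the same number correlated across genes at 0.511 to 0.918 within a genotype and at 0.397 or more over 15 pairs of groups, and 38 of 45 arrays compared correlated best with their own number, 15 of 15 for number 3 and 23 of 30 for numbers 1 and 2. All arrays compared within a genotype matched their own number, and the mismatches of numbers 1 and 2 lay between genotypes. The numbers therefore pair the samples within a genotype, and less clearly between genotypes. Each result was also fitted with the replicate number within genotype as a block. The comparison of unstimulated genotypes instead used the number shared by both genotypes. Its same-numbered arrays correlated at 0.547, 0.604 and 0.727. The first components held 43.4%, 25.1% and 11.2% of the variance. The steps were tested on simulated data with known changes.

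The alternatives were no background correction, median scaling in place of quantile normalization, the authors' log2 values, no detection filter or a stricter one (detection p under 0.01 on at least 6 arrays), the mean of a gene's probes, a fit on the groups compared only, eBayes without trend or with robust estimation, the replicate block, and leaving out each array in turn. Basophil samples named in the series description were not used here, and probes outside the gene table were tested only as a count. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.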

Results

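Transcript levels were measured on 18 Illumina mouse bead arrays, hybridised with RNA of mast cells grown from the bone marrow of C57BL/6J mice aged 4 to 6 weeks. The cells came from wild-type (WT) mice and from ST2 knockout (ST2KO) mice, which lack ST2, the receptor chain for the cytokine IL-33, encoded by Il1rl1. Cells of each genotype were left unstimulated, activated through IgE for 4 h or stimulated with IL-33 for 4 h, with 3 arrays in each of the 6 groups. The median intensity was 86.4 to 97.9 on the 17 complete arrays, and 35.1% to 38.6% of their probes were detected. The remaining array, ST2KO IgE replicate 3, held an intensity for part of its probes only. The number of arrays limited the precision: the median 95% interval reached 0.46 log2 units to either side for a comparison of 2 groups and 0.65 for a difference between responses. Changes are log2 fold changes with their standard error (SE) from 10529 genes tested, n = 3 arrays per group, and all adjusted p are from limma. Il1rl1 itself was not analysed here, since no probe carried its name in the gene table, so the genotype labels were not checked on the targeted gene.

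In all 6 groups the array numbered 3 stood apart from those numbered 1 and 2. Across genes, which are not independent replicates, arrays 1 and 2 of a group correlated at 0.992 to 0.994 and arrays 1 and 3 at 0.935 to 0.968. In every group, 148 genes were over 2-fold higher and 83 over 2-fold lower on array 3 than the mean of arrays 1 and 2, against 0 between arrays 1 and 2. On array 3, cholesterol synthesis genes were lower by a median of -1.62 log2 units over the groups, with 9 of 17 members over 2-fold lower in every group, and cell cycle genes by a median of -1.19. Of 9 mast cell proteases measured, 4 were over 2-fold higher on array 3 in every group and 1 was lower. Of 13 macrophage and dendritic cell markers, 4 were higher and 0 lower. The p-values measure only the spread between these arrays.

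In WT mast cells, IgE activation was compared with no stimulation. It raised 561 genes and lowered 688 of the 10529 tested; 292 rose and 252 fell at least 2-fold. The largest rise was in Fxyd6, which encodes a regulator of the sodium pump, at 62.4-fold (log2 5.96 ± 0.40 SE, n = 3, adjusted p = 2.06e-06). Egr2, an immediate-early transcription factor gene, rose by 5.94 ± 0.54 (adjusted p = 1.72e-05), and the chemokine genes Ccl1 and Ccl7 by 5.93 (95% interval 3.79 to 8.06) and 5.24 ± 0.76 (adjusted p = 0.00142 and 0.000543). Hdc, the gene of the enzyme that makes histamine, rose by 2.77 ± 0.37 (adjusted p = 0.00026), and Il15, a cytokine gene, fell by 2.83 ± 0.29 (adjusted p = 4.29e-05).

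The other large rises with IgE were in Tnfrsf9, a co-stimulatory receptor gene (4.54 ± 0.71, adjusted p = 0.000854), Gadd45b (3.90 ± 0.88, adjusted p = 0.00941), Egr1 (3.69 ± 0.65, adjusted p = 0.00195), and the MAP kinase phosphatase genes Dusp5 (3.60 ± 0.45, adjusted p = 0.00018) and Dusp4 (3.52 ± 1.07, adjusted p = 0.0439). Ccl4, another chemokine gene, rose by 3.45 ± 0.66 (adjusted p = 0.00348). The largest falls were in Pigz (-3.62 ± 0.69, adjusted p = 0.00357), Lpcat2, which encodes a phospholipid acyltransferase (-3.18 ± 0.53, adjusted p = 0.00129), Ffar2, a short-chain fatty acid receptor gene (-3.07 ± 0.43, adjusted p = 0.000451), and Lrrc36 (-2.79 ± 0.56, adjusted p = 0.00496). Hvcn1, a proton channel gene (-2.77 ± 0.70, adjusted p = 0.0189), Chst8 (-2.70 ± 0.73, adjusted p = 0.0257) and Ngfr, a neurotrophin receptor gene (-2.70 ± 0.80, adjusted p = 0.0402), also fell. Egr2 and Ccl1 were detected on 1 of the 3 unstimulated arrays, Gadd45b on 2 and Lrrc36 on 1 of the 3 IgE arrays, so the sizes of these changes rest on a level near background. The rule for naming these largest changes took only genes whose 2 groups of 3 arrays did not overlap. With 1 array left out, Gadd45b missed the threshold without WT unstimulated replicate 1 (adjusted p = 0.052). Dusp4 then passed only without WT IgE replicate 3 (adjusted p = 0.0234, and up to 0.176 without another array). Hvcn1 passed only without WT IgE replicate 3 (0.00909) or WT unstimulated replicate 2 (0.0474), and reached an adjusted p of 0.0929 otherwise. Chst8 and Ngfr passed only without WT unstimulated replicate 3 (adjusted p = 0.0121 and 0.0238, up to 0.106 and 0.139 otherwise).

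Among 18 cytokine and growth factor genes measured, 4 rose with IgE and 0 fell (5 and 0 adjusted over the list alone), with a median of 1.20 (0.58 without background correction) and a camera adjusted p of 0.000682, against an adjusted p = 0.178 with an estimated correlation. Tnf, detected on 1 of the 3 unstimulated arrays, rose by 3.33 ± 0.46 (adjusted p = 0.000387) and Tgfb1 by 1.12 ± 0.15 (adjusted p = 0.000287). Il33, undetected on the 3 unstimulated arrays, was at least 4.15-fold higher (adjusted p = 0.00511). Il6 rose by 1.79 ± 0.49 (adjusted p = 0.0273), a call that in fits leaving out 1 array held only without WT IgE replicate 3 (0.0303, and up to 0.112 otherwise). Il13 stood at 1.53 ± 0.49 (adjusted p = 0.055, and 0.0116 with the replicate block) and Il4 at -0.06 ± 0.61 (adjusted p = 0.97). Of 17 chemokine genes, 6 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 0.65 (0.27 without background correction) and a camera adjusted p of 0.000682, against an adjusted p = 0.278 with an estimated correlation. Ccl2 rose by 1.73 ± 0.21 (adjusted p = 0.000156). Ccl3 rose by 3.18 ± 0.81 (adjusted p = 0.0185), a call that held only without WT IgE replicate 3 (0.0176) or WT unstimulated replicate 3 (0.0274) and reached 0.0896 without another array.

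Of 20 immediate-early and NFAT-induced genes, 8 rose and 0 fell (9 and 0 adjusted over the list alone), with a median of 0.62 (0.33 without background correction) and a camera adjusted p of 5.32e-06, against an adjusted p = 0.178 with an estimated correlation. Egr3 rose by 3.35 ± 0.60 (adjusted p = 0.00228). Of 24 genes of the NF-kB pathway and its targets, 5 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.31 (0.19 without background correction); camera gave an adjusted p of 0.0433, but 0.0685 with the replicate block, and the adjusted p = 0.637 with an estimated correlation. The inhibitor genes Nfkbid and Nfkbib rose by 1.48 ± 0.19 and 1.15 ± 0.22 (adjusted p = 0.000189 and 0.0035), while Rela, a subunit gene, stood at -0.14. Of 20 genes of the unfolded protein and amino acid response, 5 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.58 (0.38 without background correction) and a camera adjusted p of 0.000682, against an adjusted p = 0.347 with an estimated correlation. The members that rose were the serine synthesis genes Psat1 (1.72 ± 0.29, adjusted p = 0.00133) and Phgdh (undetected unstimulated and at least 2.04-fold higher, adjusted p = 0.00346), the asparagine synthetase gene Asns (1.81 ± 0.35, adjusted p = 0.00374), their regulator Atf4 (0.98 ± 0.19, adjusted p = 0.00323) and, named after its value was seen, the protein folding gene Pdia6 (1.37 ± 0.39, adjusted p = 0.0342). Whether the call of Pdia6 held with 1 array left out was not analysed here. Herpud1 and Xbp1, also on this list, stood at -0.08 and 0.04.

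Cholesterol synthesis genes had a median of 0.81 with IgE in WT cells; 0 of 17 passed in limma (0 adjusted over the list alone, and 13 higher with the replicate block), while camera gave an adjusted p of 0.0128, against an adjusted p = 0.723 with an estimated correlation. This list was lower on array 3 of each group by the -1.62 given above. Msmo1, an enzyme of the pathway, stood at 1.56 ± 0.76 (adjusted p = 0.21, and 1.63e-06 with the block). Of 18 ribosome biogenesis genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone, and 11 and 0 with the block), with a median of 0.69 and a camera adjusted p of 0.0128, against an adjusted p = 0.706 with an estimated correlation; on array 3 this list was lower by -0.74.

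The remaining lists with at least 3 members past the threshold for IgE in WT cells held genes of both directions and were not shifted as groups by camera. Of 22 negative feedback regulators 7 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.0622, 0.0281 with the block, adjusted p = 0.392 with the block and an estimated correlation), among them Rgs16 (3.21 ± 0.47, adjusted p = 0.000573) and Rgs1 (0.83 ± 0.16, adjusted p = 0.00435), which dampen G protein signals. Of 24 mast cell identity genes 3 rose and 3 fell (3 and 5 adjusted over the list alone; camera adjusted p = 0.824). Cd9, a tetraspanin gene, rose by 1.39 ± 0.23 (adjusted p = 0.00129). The stem cell factor receptor gene Kit stood at -0.42 ± 0.14 (adjusted p = 0.0679, and 0.00909 with the block) and the IgE receptor gene Fcer1a at 0.01 ± 0.10 (adjusted p = 0.963). Gata2, a transcription factor gene, fell by 0.44 ± 0.13 (adjusted p = 0.0432), a call lost without any 1 of the 6 arrays of the comparison, with an adjusted p up to 0.134. The protease gene Mcpt8 stood at 1.40 ± 1.15 (adjusted p = 0.493, and 0.00249 with the block). Of 21 components of IgE receptor signalling 1 rose and 3 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.103). The kinase gene Fyn rose by 1.76 ± 0.27 (adjusted p = 0.000807), and Pik3r1 fell by 0.96 ± 0.16 (adjusted p = 0.00122).

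Of 16 genes of the exocytosis machinery, 1 rose and 4 fell with IgE (1 and 4 adjusted over the list alone; camera adjusted p = 0.105). Stx6 rose by 1.35 ± 0.26 (adjusted p = 0.00346), and Stx3 and Unc13d, which act in granule fusion, fell by 0.97 ± 0.15 and 0.88 ± 0.15 (adjusted p = 0.000973 and 0.00124). Of 20 apoptosis regulators 3 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.092), led by the BCL2 family genes Bcl2a1d (3.31 ± 0.47, adjusted p = 0.000444) and Bcl2a1b (2.95 ± 0.45, adjusted p = 0.000807). Both were detected on 1 of the 3 unstimulated arrays, so these sizes rest on a level near background. Of 18 TNF superfamily and co-stimulation genes 2 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.307). Il4ra, the IL-4 receptor gene, fell by 1.05 ± 0.20 (adjusted p = 0.00328). Tfrc, a transferrin receptor gene on the list of erythroid markers, rose by 2.63 ± 0.39 (adjusted p = 0.000671). Of 13 genes near Il1rl1, 1 rose and 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.712). Map4k4 fell by 0.77 ± 0.16 (adjusted p = 0.00627). Of 12 housekeeping controls 0 passed with IgE, in limma or adjusted over the list alone, with a median of 0.14.

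The count for IgE in WT cells rose from 1249 to 3426 with the replicate block and to 3912 without the 6 arrays numbered 3, a set chosen after seeing the data. It was 715 without WT unstimulated replicate 1, 756 without WT unstimulated replicate 2, 647 without WT IgE replicate 1 and 594 without WT IgE replicate 2. Of the genes that passed, 44.9% were higher, against 27.6% with the arrays scaled by their medians.

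**Figure D1:**
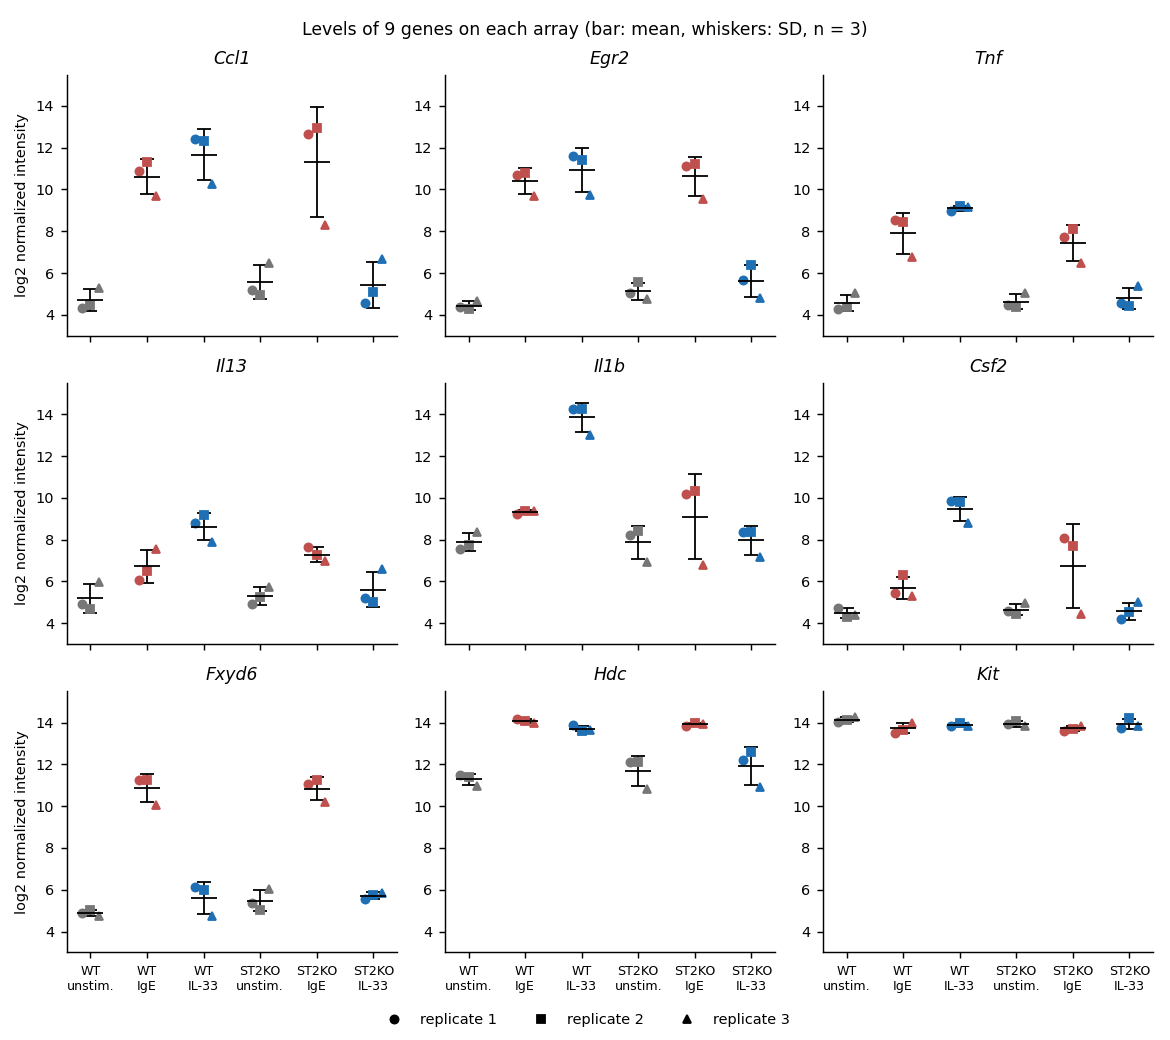
Each panel plots the log2 normalized intensity of 1 gene (Ccl1, Egr2, Tnf, Il13, Il1b, Csf2, Fxyd6, Hdc and Kit) on the y axis for the 6 groups on the x axis, with a point per array, a bar at the mean and whiskers of 1 SD (n = 3). Ccl1 stood 5.93 log2 units above the unstimulated WT arrays with IgE and 6.96 above them with IL-33, and in ST2KO cells with IL-33 it stood -0.12 from the unstimulated ST2KO arrays. Fxyd6 had a mean level of 10.86 with IgE and of 5.61 with IL-33 in WT cells.

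In WT mast cells, IL-33 was compared with no stimulation. IL-33 raised 536 genes and lowered 710 of 10529; 262 rose and 264 fell at least 2-fold. The chemokine gene Ccl1 had the largest estimate (log2 6.96, 95% interval 4.83 to 9.10, n = 3, adjusted p = 0.000397), followed by Egr2 (6.48 ± 0.54, adjusted p = 1.06e-05) and Il1b, the gene of the cytokine IL-1 beta (5.95 ± 0.73, adjusted p = 0.000139). Of 24 genes of the NF-kB pathway 18 rose, though as a list they lost their camera call with the block and an estimated correlation (adjusted p = 0.157). That call held with an estimated correlation when the 6 arrays numbered 3 were left out, a set chosen after seeing the data (camera adjusted p = 0.00266). The type 2 cytokine gene Il13 rose by 3.43 ± 0.49 (adjusted p = 0.000382). Hdc rose by 2.42 ± 0.37 (adjusted p = 0.000571), while Lyl1, a transcription factor gene of blood progenitors, fell by 1.29 ± 0.13 (adjusted p = 5e-05).

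The other large rises with IL-33 were in Gadd45b (5.64 ± 0.88, adjusted p = 0.000709), Csf2, which encodes the growth factor GM-CSF (4.99 ± 0.67, adjusted p = 0.000267), Traf1 (4.65 ± 0.54, adjusted p = 0.000105), Bcl2a1d (4.60 ± 0.47, adjusted p = 5e-05), Tnf (4.53 ± 0.46, adjusted p = 5e-05), the chemokine gene Ccl5 (4.51 ± 0.43, adjusted p = 3.02e-05) and Tnfrsf9 (4.31 ± 0.71, adjusted p = 0.00109). The largest falls were in Lpcat2 (-2.99 ± 0.53, adjusted p = 0.00192), Cited4 (-2.67 ± 0.49, adjusted p = 0.0024), Lrrc36 (-2.60 ± 0.56, adjusted p = 0.00711), Pigz (-2.49 ± 0.69, adjusted p = 0.0295), Lbh (-2.42 ± 0.72, adjusted p = 0.0393), Fgd2 (-2.39 ± 0.38, adjusted p = 0.000835), Espn (-2.38 ± 0.59, adjusted p = 0.015) and Zcchc24 (-2.26 ± 0.61, adjusted p = 0.0253). Ccl1, Egr2, Csf2, Bcl2a1d and Tnf were detected on 1 of the 3 unstimulated arrays and Gadd45b on 2, so the size and order of their changes rest on a level near background. With 1 array left out, Pigz and Zcchc24 passed only without WT IL-33 replicate 3 (adjusted p = 0.0126 and 0.00525, and up to 0.14 for each otherwise), and Lbh did not pass without any 1 of the 6 arrays (up to 0.116). Espn missed the threshold without WT IL-33 replicate 1 (adjusted p = 0.0843), WT IL-33 replicate 2 (0.0791) or WT unstimulated replicate 2 (0.0519).

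Of 24 genes of the NF-kB pathway and its targets, 18 rose with IL-33 in WT cells and 0 fell (19 and 0 adjusted over the list alone), with a median of 1.53, a camera adjusted p of 2.2e-18 and an adjusted p = 0.0315 with an estimated correlation. This call was lost with the block as well (adjusted p = 0.157), a setting in which 0 lists passed in any comparison. With the arrays numbered 3 left out 20 rose. Nfkbiz, which encodes a nuclear NF-kB cofactor, rose by 3.96 ± 0.44 (adjusted p = 7.63e-05), the subunit gene Nfkb2 by 3.11 ± 0.28 (adjusted p = 2.36e-05) and the inhibitor gene Nfkbid by 1.74 ± 0.19 (adjusted p = 5.91e-05). Rela stood at 0.22. Of 18 cytokine and growth factor genes 7 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.99 (camera adjusted p = 3.74e-06, adjusted p = 0.0315 with an estimated correlation and 0.157 with the block as well). Il6 rose by 2.81 ± 0.49 (adjusted p = 0.0017), while Il4 stood at 0.70 ± 0.61 (adjusted p = 0.525, and 0.0016 with the replicate block). Of 17 chemokine genes 7 rose and 0 fell (9 and 0 adjusted over the list alone), with a median of 0.66 and a camera adjusted p of 1.8e-05, against an adjusted p = 0.199 with an estimated correlation. Cxcl2, a neutrophil attractant gene undetected on the 3 unstimulated arrays, was at least 8.71-fold higher (adjusted p = 5.06e-05), and Ccl3 rose by 4.25 ± 0.81 (adjusted p = 0.00312).

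Of 20 immediate-early and NFAT-induced genes, 4 rose with IL-33 in WT cells and 0 fell (5 and 0 adjusted over the list alone), with a median of 0.33 (0.13 without background correction) and a camera adjusted p of 0.00459, against an adjusted p = 0.37 with an estimated correlation. Junb rose by 1.51 ± 0.27 (adjusted p = 0.00232). Of 20 genes of the unfolded protein and amino acid response 3 rose and 0 fell (5 and 0 adjusted over the list alone), with a median of 0.33 (0.21 with the arrays scaled by their medians) and a camera adjusted p of 0.0111, against an adjusted p = 0.478 with an estimated correlation. Atf4 rose by 0.93 ± 0.19 (adjusted p = 0.0043). Of 18 ribosome biogenesis genes 1 rose and 1 fell (1 and 1 adjusted over the list alone, and 11 and 1 with the block), with a median of 0.68 and a camera adjusted p of 0.00645, against an adjusted p = 0.669 with an estimated correlation. Wdr43, of the small ribosomal subunit pathway, rose by 1.20 ± 0.25 (adjusted p = 0.0054).

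Further lists held at least 3 members past the threshold for IL-33 in WT cells without a shift of the group by camera. Of 20 apoptosis regulators 5 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.0546), among them Bcl2a1b at 4.27 ± 0.45 (adjusted p = 5.06e-05). Of 24 mast cell identity genes 4 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.984), with the serotonin transporter gene Slc6a4 up by 2.88 ± 0.63 (adjusted p = 0.00744) and Cd9 by 1.28 ± 0.23 (adjusted p = 0.00232). Kit, Fcer1a and Gata2 stood at -0.27, 0.13 and -0.09 (adjusted p = 0.251, 0.458 and 0.736). Mcpt8 stood at 1.08 (adjusted p = 0.617, and 0.0138 with the block). Of 21 components of IgE receptor signalling 0 rose and 4 fell (0 and 6 adjusted over the list alone; camera adjusted p = 0.0546, 0.0489 with the block, adjusted p = 0.51 with the block and an estimated correlation), including the kinase genes Btk (-0.91 ± 0.14, adjusted p = 0.000645) and Prkca (-0.59 ± 0.12, adjusted p = 0.00375). Of 16 exocytosis genes 2 rose and 5 fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.288). Unc13d stood at -1.30 ± 0.15 (adjusted p = 7.7e-05) and Stx6 at 2.07 ± 0.26 (adjusted p = 0.000152). Of 22 negative feedback regulators 4 rose and 3 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.576). Dusp5 rose by 2.65 ± 0.45 (adjusted p = 0.00143) and Inpp5d, a lipid phosphatase gene, at -0.97 ± 0.20 (adjusted p = 0.00537). Of 18 TNF superfamily and co-stimulation genes 3 rose and 1 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.145, 0.0153 with the block, adjusted p = 0.51 with the block and an estimated correlation), with the TNF receptor gene Tnfrsf1b up by 2.73 ± 0.41 (adjusted p = 0.000527).

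The count for IL-33 in WT cells rose from 1246 to 3315 with the replicate block and to 4069 without the 6 arrays numbered 3. It was 767 without WT unstimulated replicate 1, 784 without WT unstimulated replicate 2, 624 without WT IL-33 replicate 1, 695 without WT IL-33 replicate 2 and 755 when fitted on the 2 groups alone. Of the genes that passed, 43.0% were higher, against 18% with the arrays scaled by their medians, which shifted the median of all genes from -0.02 to -0.16; the medians of the 6 shifted lists stayed above 0 under this scaling, from 0.21 to 1.34.

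The 2 stimuli were compared with each other directly in WT cells. Of 10529 genes, 227 were higher and 239 lower with IL-33 than with IgE; 152 and 122 differed at least 2-fold. Higher with IL-33 were Il1b (4.54 ± 0.73, n = 3, adjusted p = 0.00172), Csf2 (3.79 ± 0.67, adjusted p = 0.00356) and 14 of 24 genes of the NF-kB pathway and its targets. Of 17 interferon-response genes 3 were higher, such as Rsad2, an antiviral gene (3.25 ± 0.62, adjusted p = 0.00591). Fxyd6 was far lower with IL-33 (-5.25 ± 0.40, adjusted p = 4.1e-06), as was Rgs16 (-3.10 ± 0.47, adjusted p = 0.00101), which was detected on 1 of the 3 IL-33 arrays.

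The largest other differences in favour of IL-33 were in Asb2, a ubiquitin ligase gene (4.75 ± 0.89, adjusted p = 0.00543), Milr1, an inhibitory mast cell receptor gene (4.41 ± 0.70, adjusted p = 0.00153), Cxcl16 (3.82 ± 0.56, adjusted p = 0.00089), Tnfaip2 (3.78 ± 0.54, adjusted p = 0.00066), Cd72 (3.76 ± 0.32, adjusted p = 1.09e-05), Gbp3, an interferon-inducible GTPase gene (3.72 ± 0.93, adjusted p = 0.0318), and Nfkbiz (3.51 ± 0.44, adjusted p = 0.00022). In favour of IgE they were in Lbh (-3.05 ± 0.72, adjusted p = 0.0228), Dok2, an adaptor gene (-3.04 ± 0.50, adjusted p = 0.00196), Tm6sf1 (-2.83 ± 0.60, adjusted p = 0.0125), Mcf2l (-2.82 ± 0.43, adjusted p = 0.00117) and Rpp25 (-2.67 ± 0.40, adjusted p = 0.00101), and in Slc37a2, undetected on the 3 IL-33 arrays and at least 8.08-fold lower there (adjusted p = 0.0206). With 1 array left out, Gbp3 and Slc37a2 passed only without WT IgE replicate 3 (adjusted p = 0.0156 and 0.00189, up to 0.148 and 0.122 otherwise). Lbh passed only without WT IgE replicate 3 (adjusted p = 0.00656) or WT IL-33 replicate 2 (0.0473), with up to 0.127 otherwise. Tm6sf1 missed the threshold without WT IL-33 replicate 1 (adjusted p = 0.0658) or replicate 2 (0.0642).

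Of 24 genes of the NF-kB pathway and its targets, 14 were higher with IL-33 than with IgE and 0 lower (19 and 0 adjusted over the list alone), with a median of 1.18 (0.78 without background correction), a camera adjusted p of 2.87e-20 and an adjusted p = 0.0444 with an estimated correlation. This call was lost with the block as well (adjusted p = 0.237), as were all calls in that setting. Nfkbia, the gene of the inhibitor IkB alpha, differed by 3.10 ± 0.51 (adjusted p = 0.00209) and Nfkb2 by 1.90 ± 0.28 (adjusted p = 0.000858), while Sod2 stood at 0.04. Of 17 interferon-response genes 3 were higher and 0 lower (10 and 0 adjusted over the list alone), with a median of 0.84 (0.43 without background correction) and a camera adjusted p of 4.66e-07, against an adjusted p = 0.267 with an estimated correlation. With the arrays numbered 3 left out, 13 of these 17 were higher, and camera with an estimated correlation gave an adjusted p of 0.0212. Irf1 stood at 1.04 (adjusted p = 0.356, and 0.000834 with the replicate block). Of 17 chemokine genes 3 were higher and 1 lower (5 and 3 adjusted over the list alone; camera adjusted p = 0.542): Cxcl2, detected on 1 of the 3 IgE arrays, differed by 2.91 ± 0.36 (adjusted p = 0.000172), Ccl5 by 3.04 ± 0.43 (adjusted p = 0.000595), and Ccl2, a monocyte attractant gene, by -1.21 ± 0.21 (adjusted p = 0.00333). Of 18 cytokine genes 3 were higher and 0 lower (4 and 2 adjusted over the list alone; camera adjusted p = 0.135, 0.0214 with the block, adjusted p = 0.471 with the block and an estimated correlation). Il13 differed by 1.91 ± 0.49 (adjusted p = 0.0367), a call that in fits leaving out 1 array held only without WT IgE replicate 3 (0.0153) or WT IL-33 replicate 3 (0.0223) and reached 0.188 otherwise. Il6, Il4 and Tnf differed by 1.02, 0.75 and 1.19 (adjusted p = 0.346, 0.694 and 0.207; 0.00117, 0.00162 and 0.0832 with the block), Gata2 by 0.35 (adjusted p = 0.199, and 0.0135 with the block) and Hdc by -0.35 (adjusted p = 0.795).

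Other lists with at least 3 members that differed between the stimuli were not shifted as groups. Of 22 negative feedback regulators 0 were higher with IL-33 and 3 lower (1 and 3 adjusted over the list alone; camera adjusted p = 0.261), including Rgs1 at -1.21 ± 0.16 (adjusted p = 0.000453). Of 21 components of IgE receptor signalling 2 were higher and 2 lower (3 and 3 adjusted over the list alone; camera adjusted p = 0.623). Vav1 differed by 0.75 ± 0.14 (adjusted p = 0.00518) and Fyn by -1.51 ± 0.27 (adjusted p = 0.00394). Of 24 mast cell identity genes 2 were higher and 1 lower (2 and 1 adjusted over the list alone; camera adjusted p = 0.865). Lyl1 differed by -0.86 ± 0.13 (adjusted p = 0.00123). Of 18 TNF superfamily and co-stimulation genes 2 were higher and 1 lower (2 and 1 adjusted over the list alone; camera adjusted p = 0.623), with the activation marker Cd69 at 3.19 ± 0.62 (adjusted p = 0.00684). Of 20 genes of the unfolded protein and amino acid response 0 were higher and 3 lower (2 and 3 adjusted over the list alone; camera adjusted p = 0.542). Phgdh, the first enzyme of serine synthesis, was undetected on the 3 IL-33 arrays and at least 1.93-fold lower there (adjusted p = 0.00535).

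Both stimuli raised 211 genes and lowered 379, against 28.6 and 46.4 if the lists were independent, although the shared unstimulated arrays alone raise such overlaps. Of the 536 genes raised by IL-33, 134 were higher and 11 lower with IL-33 than with IgE in the direct test; of the 561 raised by IgE, 140 were higher and 11 lower with IgE. The count of the direct comparison rose from 466 to 1667 with the replicate block and to 2199 without the 6 arrays numbered 3. It was 224 without WT IgE replicate 1, 240 without WT IgE replicate 2, 246 without WT IL-33 replicate 1, 261 without WT IL-33 replicate 2 and 294 when fitted on the 2 groups alone.

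**Figure D2:**
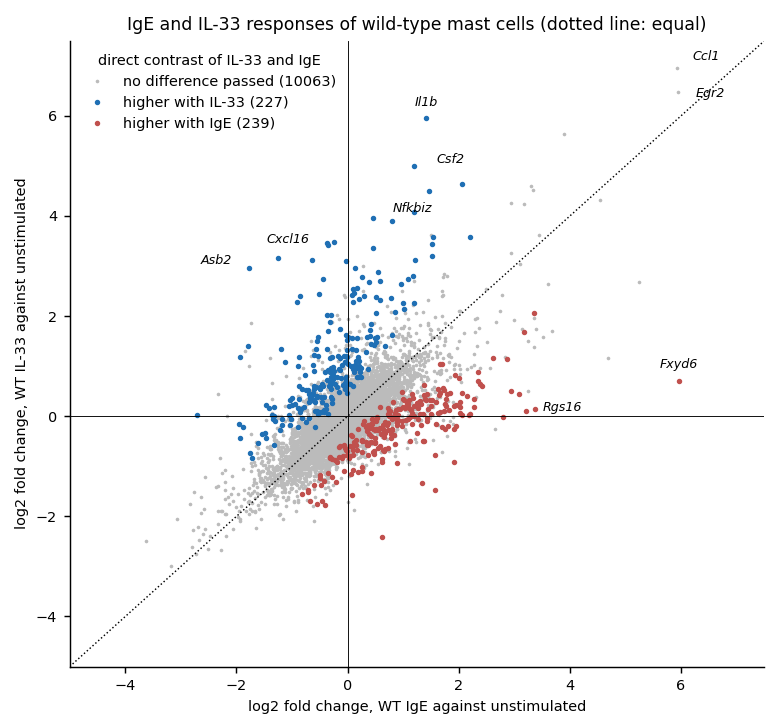
Each point is a gene, with its log2 fold change in WT cells with IgE on the x axis and with IL-33 on the y axis. The 227 genes higher with IL-33 in the direct comparison are blue, the 239 higher with IgE are red, and the others are grey. Fxyd6 lies far to the IgE side (5.96 with IgE).

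In ST2KO mast cells, IgE activation raised 577 genes and lowered 749 of 10529; 308 rose and 276 fell at least 2-fold. Ccl1 rose by 5.75 (95% interval 3.61 to 7.88, n = 3, adjusted p = 0.00188), Egr2 by 5.50 ± 0.54 (adjusted p = 3.87e-05) and Fxyd6 by 5.35 ± 0.40 (adjusted p = 4.68e-06). Tnf rose by 2.81 ± 0.46 (adjusted p = 0.00127) and Hdc by 2.24 ± 0.37 (adjusted p = 0.0012), while Il15 fell by 2.87 ± 0.29 (adjusted p = 4.13e-05). The comparison asks what the IgE response is in cells without ST2.

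Large rises with IgE in ST2KO cells were also in Tnfrsf9 (4.35 ± 0.71, adjusted p = 0.00119), Ccl7 (4.21 ± 0.76, adjusted p = 0.00235), Gzmd, a granzyme gene (4.06 ± 0.71, adjusted p = 0.00199), Tnfsf14 (3.51 ± 0.84, adjusted p = 0.0139), Ccl4 (3.41 ± 0.66, adjusted p = 0.00355), Bcl2a1d (3.38 ± 0.47, adjusted p = 0.000414) and Gadd45b (3.38 ± 0.88, adjusted p = 0.0208). Falls were largest in Pigz (-3.31, adjusted p = 0.00625), Lpcat2 (-3.16, adjusted p = 0.00145), Agap1 (-2.74, adjusted p = 0.043), Zfp521 (-2.74, adjusted p = 0.00319), Lrrc36 (-2.73, adjusted p = 0.00565), Cx3cr1, a chemokine receptor gene (-2.72, adjusted p = 0.0255), and Nxpe4 (-2.69, adjusted p = 0.0231). Gzmd, Bcl2a1d and Tnf were detected on 1 of the 3 unstimulated ST2KO arrays, and Lrrc36 on 1 of the 3 with IgE, so these sizes rest on a level near background. With 1 array left out, Tnfsf14 missed the threshold without ST2KO unstimulated replicate 3 (adjusted p = 0.0607), ST2KO IgE replicate 1 (0.0621) or ST2KO IgE replicate 2 (0.0644). Gadd45b passed only without ST2KO unstimulated replicate 3 (adjusted p = 0.00468) or ST2KO IgE replicate 1 (0.0384), Agap1 only without ST2KO IgE replicate 3 (0.0423) and Cx3cr1 only without ST2KO unstimulated replicate 3 (0.00167). Nxpe4 passed only without ST2KO unstimulated replicate 1 (adjusted p = 0.0347) or ST2KO IgE replicate 3 (0.00581). Otherwise the adjusted p of these 4 genes reached 0.0918, 0.163, 0.11 and 0.113.

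Of 18 cytokine and growth factor genes, 7 rose with IgE in ST2KO cells and 0 fell (10 and 1 adjusted over the list alone), with a median of 1.26 and a camera adjusted p of 7.82e-05, against an adjusted p = 0.0986 with an estimated correlation. Tgfb1 rose by 1.08 (adjusted p = 0.000414), and Il13 by 1.97 ± 0.49 (adjusted p = 0.0164), a call that held only without ST2KO unstimulated replicate 3 (0.0222) or ST2KO IgE replicate 3 (0.0192) and reached 0.0745 without another array. Il6 stood at 1.28 ± 0.49 (adjusted p = 0.102, and 8.95e-05 with the replicate block). Of 17 chemokine genes 8 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.82 (0.31 without background correction) and a camera adjusted p of 7.82e-05, against an adjusted p = 0.244 with an estimated correlation. Ccl2 rose by 1.25 (adjusted p = 0.00151) and Ccl3 by 3.39 (adjusted p = 0.013); the call of Ccl3 was lost without ST2KO unstimulated replicate 1 (0.0562), ST2KO IgE replicate 1 (0.0731) or ST2KO IgE replicate 2 (0.0715). Of 20 immediate-early and NFAT-induced genes 6 rose and 0 fell (9 and 0 adjusted over the list alone), with a median of 0.60 (0.25 without background correction) and a camera adjusted p of 0.000114, against an adjusted p = 0.244 with an estimated correlation. Egr1 rose by 3.19 (adjusted p = 0.00497).

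Of 20 genes of the unfolded protein and amino acid response, 7 rose with IgE in ST2KO cells and 0 fell (8 and 0 adjusted over the list alone), with a median of 0.66 and a camera adjusted p of 7.82e-05, against an adjusted p = 0.244 with an estimated correlation. Psat1 rose by 1.88 (adjusted p = 0.000833) and Asns by 1.95 (adjusted p = 0.0023). Of 24 NF-kB genes 6 rose and 0 fell (7 and 1 adjusted over the list alone), with a median of 0.21 and a camera adjusted p of 0.00976, against an adjusted p = 0.616 with an estimated correlation. Nfkbid rose by 1.38 (adjusted p = 0.000377). Cholesterol synthesis genes had a median of 0.69 with 0 of 17 past the threshold of limma (0 adjusted over the list alone, and 13 higher with the block) and a camera adjusted p of 0.00976, against an adjusted p = 0.716 with an estimated correlation. Ribosome biogenesis genes had a median of 0.64 with 0 of 18 past it (0 adjusted over the list alone, and 11 higher with the block) and a camera adjusted p of 0.00913, against an adjusted p = 0.716 with an estimated correlation.

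Lists of both directions with IgE in ST2KO cells were not shifted as groups. They included 22 negative feedback regulators (6 rose and 1 fell; 8 and 1 adjusted over the list alone; camera adjusted p = 0.0585, 0.0186 with the block, adjusted p = 0.49 with the block and an estimated correlation), such as Rgs16 at 3.23 (adjusted p = 0.000606), and 18 TNF superfamily genes (4 and 1; 5 and 1 adjusted over the list alone; camera adjusted p = 0.0559). Of 21 components of IgE receptor signalling 3 rose and 4 fell (3 and 6 adjusted over the list alone; camera adjusted p = 0.134). Fyn rose by 1.67 (adjusted p = 0.00111). Of 16 exocytosis genes 1 rose and 4 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.181). Unc13d fell by 0.88 (adjusted p = 0.00127). Of 20 apoptosis regulators 4 rose and 1 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.246). Bcl2a1b rose by 2.80 (adjusted p = 0.00111). Of 18 components of IL-33 receptor signalling 3 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.784). Mapk8, a stress kinase gene, fell by 1.28 ± 0.29 (adjusted p = 0.0103), a call lost without ST2KO IgE replicate 1 (0.0517) or 2 (0.0524). Of 13 genes near Il1rl1 1 rose and 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.769). Of 24 mast cell identity genes 3 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.784). Kit stood at -0.24 (adjusted p = 0.3) and Gata2 at -0.38 (adjusted p = 0.0776, and 0.00398 with the block). Tfrc rose by 3.02 ± 0.39 (adjusted p = 0.000285). The count for IgE in ST2KO cells rose from 1326 to 3558 with the block and to 3880 without the 6 arrays numbered 3. It was 753 without ST2KO unstimulated replicate 2, 658 without ST2KO IgE replicate 1, 679 without ST2KO IgE replicate 2 and 483 when fitted on the 2 groups alone. Of the genes that passed, 43.5% were higher, against 28.3% with the arrays scaled by their medians.

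The IgE responses of the 2 genotypes were then compared by their interaction. Of the 1249 genes called in WT cells, 1245 moved in the same direction in ST2KO cells and 912 passed there too, and the slope of the ST2KO on the WT change was 0.924. The difference between genotypes (ST2KO minus WT) was -0.61 for Fxyd6 (95% interval -1.81 to 0.60), -0.44 for Egr2 (-2.06 to 1.18), -0.03 for Il15 (-0.92 to 0.85) and -0.18 for Ccl1 (-3.20 to 2.84). In limma 0 of 10529 genes passed, with 133 at an unadjusted p under 0.05 (1.26%) and 0 also with the replicate block (298 unadjusted); 0 lists were shifted by camera or fry. Intervals as wide as that of Ccl1 leave large differences open, so a like response is not shown gene by gene. Without the 6 arrays numbered 3 the count was 15, and camera shifted 6 lists: chemokines, cholesterol synthesis and the unfolded protein and amino acid response (adjusted p = 0.000237 each), immediate-early genes (0.00503), cytokines (0.0212) and cell cycle (0.0315). With an estimated correlation none of the 6 passed (adjusted p = 0.325 to 0.747).

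In ST2KO cells, IL-33 was compared with no stimulation. The genes that IL-33 moved in WT cells stayed near their unstimulated level: Ccl1 stood at -0.12 (95% interval -2.25 to 2.01), Egr2 at 0.49 (-0.66 to 1.64), Il1b at 0.11 (-1.44 to 1.66), Tnf at 0.16 (-0.83 to 1.14) and Il13 at 0.30 ± 0.49 SE (n = 3). The 536 genes raised in WT cells, with a median of 0.99 there, had a median of 0.01 in ST2KO cells (quartiles -0.08 and 0.11). The 710 lowered genes had medians of -0.86 and -0.03 (quartiles -0.13 and 0.05), and 0 of the 1246 changed over 2-fold. Across all genes tested, 0 passed in limma, and the largest change was 0.77 in size. At an unadjusted p under 0.05 there were 155 (1.47%), again below a share of 0.05. With the replicate block 0 passed (390 unadjusted). Of 27 lists 0 were shifted by camera or fry, and 1 by camera with the block, glycolysis and hypoxia response (median 0.13, camera adjusted p = 0.0135 with the block, adjusted p = 0.995 with the block and an estimated correlation).

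On simulated data for this comparison with all 10529 genes, 43.3% of 67 genes changed 2-fold and 87.9% of 66 genes changed 4-fold were recovered. Only 11.9% of 67 changed 1.5-fold were, so smaller changes could have been missed. The changed genes were drawn only from genes above a set level in unstimulated ST2KO cells, so recovery near background was not measured. With the block 95.5%, 100% and 46.3% were recovered, and 15 of 10329 unchanged genes passed, against 0 without it. The simulated arrays of a genotype shared their replicate effects, so a gain with the block was built in.

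The difference in the IL-33 response between genotypes was tested directly. In ST2KO cells 154 genes responded lower than in WT cells and 132 higher, of 10529 tested, 123 and 94 of them by at least 2-fold. The 154 were all among the genes raised by IL-33 in WT cells and the 132 all among those it lowered. This overlap was largely set by the construction, since the difference includes the WT response on the same arrays. ST2KO minus WT, the response of Ccl1 differed by -7.08 ± 1.42 (SE, n = 3, adjusted p = 0.0157), that of Egr2 by -5.98 ± 0.76 (adjusted p = 0.00177), that of Il1b by -5.84 ± 1.03 (adjusted p = 0.00828) and that of Csf2 by -5.07 ± 0.95 (adjusted p = 0.0109). Of 24 NF-kB genes 11 were lower, though the list lost its camera call with the block and an estimated correlation (adjusted p = 0.124).

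Gadd45b differed by -5.57 ± 1.24 (adjusted p = 0.0279), Ccl5 by -4.78 ± 0.60 (adjusted p = 0.00177), Tnf by -4.37 ± 0.65 (adjusted p = 0.00473), Il13 by -3.13 ± 0.69 (adjusted p = 0.0265), Il6 by -2.94 ± 0.69 (adjusted p = 0.0379) and Hdc by -2.19 ± 0.52 (adjusted p = 0.0379). Ccl3 differed by -4.37 ± 1.14 (adjusted p = 0.0546, and 0.0119 with the replicate block). The largest positive differences, in genes that IL-33 lowered in WT cells, were in Lpcat2 (3.0 ± 0.75, adjusted p = 0.0465), Fgd2 (2.30 ± 0.54, adjusted p = 0.0368), Ogfrl1 (2.09 ± 0.33, adjusted p = 0.00483), Carhsp1 (1.95 ± 0.48, adjusted p = 0.0454), Pwwp3a (1.87 ± 0.41, adjusted p = 0.0268) and Rcbtb2 (1.85 ± 0.35, adjusted p = 0.0112).

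Unstimulated WT cells had Ccl1, Egr2, Csf2 and Tnf detected on 1 of 3 arrays, so the sizes of these differences rest on a level near background. In fits leaving out 1 of the 12 arrays, the difference of Ccl1 missed the threshold without WT IL-33 replicate 1 (adjusted p = 0.0564) or replicate 2 (0.0557). That of Gadd45b missed it without replicate 1 or 2 of the WT unstimulated, WT IL-33 or ST2KO IL-33 group (up to 0.0877). Il13 passed only without WT unstimulated replicate 3 (0.0157), WT IL-33 replicate 3 (0.0102), ST2KO unstimulated replicate 1 (0.0438) or ST2KO IL-33 replicate 3 (0.0116), and reached 0.087 otherwise. Il6 passed only without WT IL-33 replicate 3 (0.0302), ST2KO unstimulated replicate 3 (0.0324) or ST2KO IL-33 replicate 1 (0.0445), and reached 0.108. Hdc passed only without WT IL-33 replicate 3 (0.0353), ST2KO unstimulated replicate 3 (0.0137), ST2KO IL-33 replicate 2 (0.0246) or ST2KO IL-33 replicate 3 (0.0381), and reached 0.108. Lpcat2 passed only without WT IL-33 replicate 3 (0.000663), with up to 0.136 otherwise. Fgd2 passed only without WT IL-33 replicate 3 (0.0227), ST2KO unstimulated replicate 2 (0.0233) or 3 (0.0491), or ST2KO IL-33 replicate 3 (0.019), and reached 0.108. Carhsp1 passed only without WT IL-33 replicate 3 (0.0291), ST2KO unstimulated replicate 3 (0.0402) or ST2KO IL-33 replicate 1 (0.049), and reached 0.136. Pwwp3a passed only without WT unstimulated replicate 3 (0.0418), WT IL-33 replicate 3 (3.2e-05) or ST2KO unstimulated replicate 3 (0.0464), and reached 0.0862.

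In all, 8 lists differed in their IL-33 response between genotypes, all lower in ST2KO cells by camera. Of 24 NF-kB genes 11 were lower and 0 higher (18 and 0 adjusted over the list alone), with a median of -1.63, a camera adjusted p of 1.64e-19 and an adjusted p = 0.0255 with an estimated correlation. This call was lost with the block as well (adjusted p = 0.124). With the arrays numbered 3 left out 19 were lower, and camera with an estimated correlation gave an adjusted p of 0.00171. The cytokine, chemokine, immediate-early, interferon and ribosome biogenesis lists then stood at 0.0475 to 0.0492. The apoptosis and the unfolded protein and amino acid lists stood at 0.196 each. Nfkbiz differed by -4.03 ± 0.62 (adjusted p = 0.00483) and Nfkb2 by -3.07 ± 0.40 (adjusted p = 0.00177). Of 18 cytokine genes 7 were lower and 0 higher (7 and 0 adjusted over the list alone), with a median of -1.05 (camera adjusted p = 3.43e-06, adjusted p = 0.0255 with an estimated correlation and 0.124 with the block as well). Of 17 chemokine genes 4 were lower (7 adjusted over the list alone), with a median of -0.79 (-0.36 without background correction; camera adjusted p = 1.06e-05, adjusted p = 0.223 with an estimated correlation), such as Cxcl2 (adjusted p = 0.00483). No size is given for Cxcl2, which was undetected on the unstimulated arrays of both genotypes. Of 20 immediate-early genes 2 were lower (2 adjusted over the list alone), with a median of -0.33 (-0.13 without background correction and -0.58 in the authors' values; camera adjusted p = 0.0134, adjusted p = 0.494 with an estimated correlation). Of 20 apoptosis regulators 3 were lower (3 adjusted over the list alone), with a median of -0.17 that turned to 0.06 with the arrays scaled by their medians and was -0.11 without background correction (camera adjusted p = 0.033, and 0.0706 with the block, adjusted p = 0.272 with an estimated correlation). These 3 were Bcl2a1b (-4.53 ± 0.64, adjusted p = 0.00363), Bcl2a1d (-4.65 ± 0.66, adjusted p = 0.00363) and Bcl2a1c (adjusted p = 0.00483), which encode relatives of BCL2 that oppose cell death. Bcl2a1d and Bcl2a1b were detected on 1 of 3 unstimulated WT arrays, so their sizes rest on a level near background. Bcl2a1c was undetected in ST2KO cells with and without IL-33 and in unstimulated WT cells, so no size is given. The interferon (median -0.29, camera adjusted p = 0.0473), unfolded protein and amino acid (-0.40, 0.0447) and ribosome biogenesis lists (-0.56, 0.0207) had 0 members past the threshold of limma (0 adjusted over each list alone; 4, 4 and 7 lower with the block, and 1 of the second list higher), and an adjusted p = 0.625, 0.625 and 0.791 with an estimated correlation. Their medians were -0.17, -0.14 and -0.32 with the arrays scaled by their medians, and the first 2 were -0.11 and -0.25 without background correction. Of 18 TNF superfamily and co-stimulation genes 1 was higher and 2 were lower (1 and 3 adjusted over the list alone; camera adjusted p = 0.311, 0.0221 with the block, adjusted p = 0.557 with the block and an estimated correlation). Tnfrsf1b differed by -3.01 ± 0.58 (adjusted p = 0.0122).

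The count of genes with a different IL-33 response rose from 286 to 1639 with the replicate block and to 2563 without the 6 arrays numbered 3. It was 122 and 134 without WT unstimulated replicate 1 and 2, 99 and 109 without WT IL-33 replicate 1 and 2, 577 without WT IL-33 replicate 3, 143 and 161 without ST2KO unstimulated replicate 1 and 2, and 140 and 140 without ST2KO IL-33 replicate 1 and 2. It was 141 on the 4 groups alone and 145 with no detection filter. Of the genes that passed, 46.2% were higher in ST2KO cells, against 80.1% with the arrays scaled by their medians, which moved the median of all genes from 0.02 to 0.20.

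**Figure D3:**
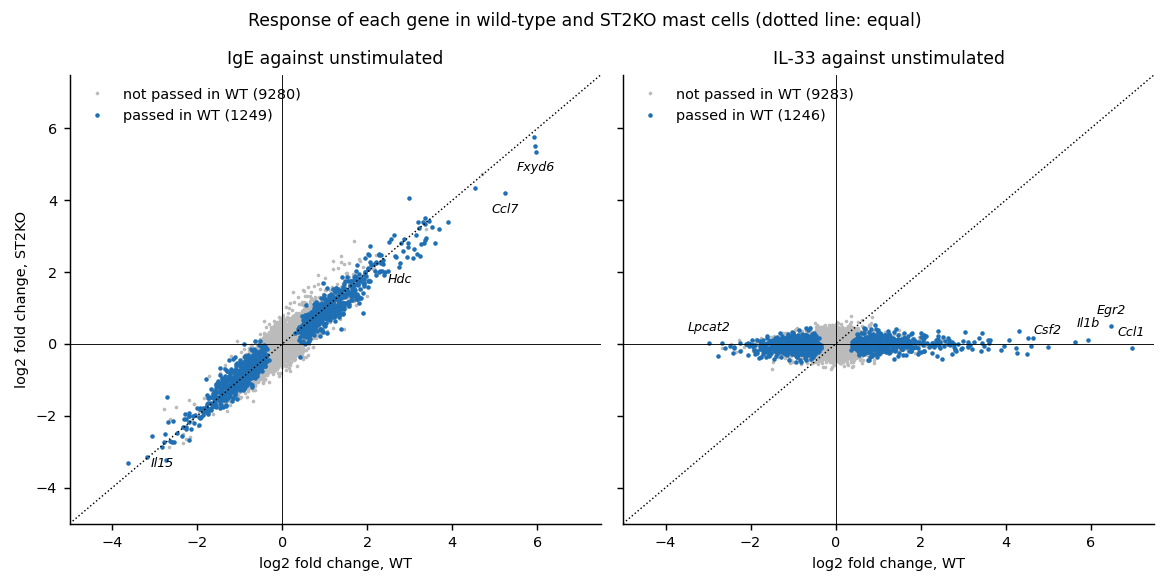
Each point is a gene, with its log2 fold change in WT cells on the x axis and in ST2KO cells on the y axis, for IgE (left) and IL-33 (right); genes that passed in WT cells, 1249 and 1246, are blue. The blue points follow the diagonal for IgE (slope 0.924) and lie flat for IL-33 (slope 0.0191).

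**Figure D4:**
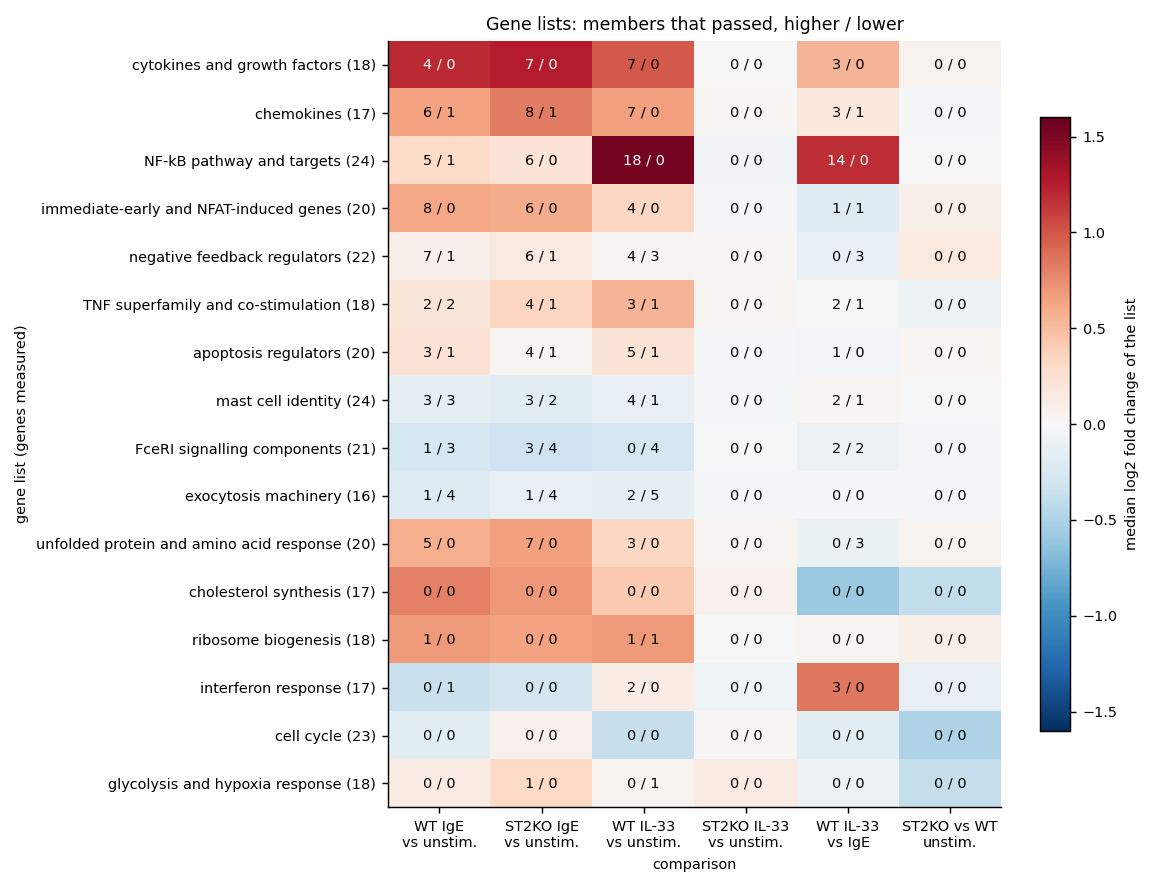
The heat map gives the median log2 fold change of each gene list (y axis) in 6 comparisons (x axis) as colour, with the number of members that passed higher and lower written in each cell. The NF-kB list had its highest median with IL-33 in WT cells (1.53) and 18 members higher there.

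Unstimulated ST2KO and WT cells differed in 1 gene of 10529: Rpe, an enzyme gene of the pentose phosphate pathway, was 5.22-fold lower in ST2KO cells (log2 -2.38 ± 0.29 SE, n = 3, adjusted p = 0.0051). Its level was lower in ST2KO cells in all 3 conditions, at 5.30, 4.64 and 4.99 unstimulated, with IgE and with IL-33, against 7.68, 6.84 and 7.87 in WT cells. Kit, Fcer1a, Hdc, Tnf and Il13 did not pass (adjusted p = 1 each). Cell cycle genes had a median of -0.49 and glycolysis and hypoxia genes of -0.38 in ST2KO cells, with 0 of 23 and 0 of 18 members past the threshold of limma (0 adjusted over each list alone). Camera gave an adjusted p of 1.76e-05 and 5.53e-05, against an adjusted p = 0.889 for each with an estimated correlation, and fry 0.933 for each. Both lists also differed between replicates: on array 3 of the unstimulated groups, cell cycle genes had a median of -1.03 in WT and -1.92 in ST2KO cells, and glycolysis genes of -0.81 and 0.11. The call of Rpe was lost without ST2KO unstimulated replicate 1 (adjusted p = 0.057) or replicate 2 (0.0649), which left 0 genes, while 6 genes passed without WT unstimulated replicate 3. At an unadjusted p under 0.05 there were 339 genes (3.22%), also below a share of 0.05. With the replicate block 7 genes were higher and 14 lower, 21 in all including Rpe (adjusted p = 0.000352). Without the 6 arrays numbered 3, 533 genes passed and 11 of the 18 glycolysis genes were lower. With the arrays scaled by their medians the median of all genes moved from 0.01 to -0.12, and the 2 lists lay at -0.65 and -0.50. Cell cycle genes lay at -0.32 without background correction.

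Markers of other cell types, measured for basophils (6 genes), neutrophils (5), macrophages and dendritic cells (13), eosinophils (2), lymphocytes (4) and the erythroid and megakaryocyte lineage (8), were not shifted as lists by camera in any of the 8 comparisons. With the replicate block, the macrophage and dendritic cell list had a median of 0.30 for IL-33 over IgE in WT cells (camera adjusted p = 0.0127) and of -0.41 for ST2KO over WT unstimulated cells (camera adjusted p = 0.00438), and the erythroid list of -0.34 in the latter (camera adjusted p = 0.0357). With the block and an estimated correlation these calls were lost (adjusted p = 0.436, 0.483 and 0.483). Without the 6 arrays numbered 3 the macrophage list stood at 0.31 for IL-33 over IgE (camera adjusted p = 0.0178, adjusted p = 0.443 with an estimated correlation). For ST2KO over WT it then stood at -0.02 (camera adjusted p = 0.536) and the erythroid list at -0.41 (camera adjusted p = 0.035, adjusted p = 0.209 with an estimated correlation). Clec7a, a macrophage lectin gene, was undetected in unstimulated ST2KO cells and at least 1.6-fold higher with IgE (adjusted p = 0.000693). Cd8b1, a T cell marker, was lower with IL-33 in WT cells (-1.0 ± 0.20, adjusted p = 0.00511) and with IgE in WT (-0.90 ± 0.20, adjusted p = 0.00958) and ST2KO cells (-0.95 ± 0.20, adjusted p = 0.00714). Its call with IgE in WT cells was lost without WT IgE replicate 2 (adjusted p = 0.0538). Nkg7, a gene of cytotoxic granules, was undetected unstimulated and at least 1.84-fold higher with IgE in WT cells (adjusted p = 0.0174) and 2.02-fold in ST2KO cells (adjusted p = 0.00924). Its calls were lost without WT unstimulated replicate 1 (adjusted p = 0.0588) or WT IgE replicate 1 (0.0962), and without ST2KO IgE replicate 1 (0.0536) or 2 (0.0531).

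Across all 10529 genes, which are not independent replicates, 3 correlations of log2 fold changes were computed. The WT and ST2KO responses to IgE correlated at 0.924 (jackknife SE 0.064) and the WT and ST2KO responses to IL-33 at 0.107 (0.094), pairs that share no arrays. The WT responses to IgE and IL-33, which share the unstimulated arrays, correlated at 0.678 (0.084), against 0.498 simulated for unchanged groups with the same controls, with covariances of 0.246 and 0.0188.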

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

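Of the tests in this part, that of too little power in the ST2KO arrays was chosen only after its result had been seen. The IL-33 response differed between ST2KO and WT cells in 286 genes by a test of the difference itself. As ST2KO minus WT on the log2 scale, the difference was 3.0 for Lpcat2, 2.30 for Fgd2, 2.09 for Ogfrl1, 1.95 for Carhsp1, 1.87 for Pwwp3a and 1.85 for Rcbtb2. It was -7.08 for Ccl1, -5.98 for Egr2, -5.84 for Il1b, -5.57 for Gadd45b, -5.07 for Csf2, -4.78 for Ccl5, -4.37 for Tnf, -3.13 for Il13, -2.94 for Il6 and -2.19 for Hdc.

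Too little power in the ST2KO arrays could leave ST2KO cells without a gene called for IL-33. IgE gave 1326 genes against the same unstimulated arrays, which argues against this for a response as wide as that to IgE. The spread was pooled over all 18 arrays, so this count does not measure the ST2KO arrays alone. Fitted on the 2 groups alone, IgE gave 483 genes in ST2KO and 1341 in WT cells. As 43.3% of simulated 2-fold changes were recovered, single genes changed 2-fold or less could have been missed. Of 100 assignments of genotype within the 2 conditions, 9 gave at least as many genes as the real 286, the highest other 503, so chance was not excluded by this count. All 9 kept the IL-33 arrays parted by genotype, as 12 of the 100 did with at least 192 genes each, while the 88 others gave at most 1. The count thus rests on the genotype of the IL-33 arrays, and exchanging labels among unstimulated arrays alone moved it between 192 and 503. Loss of ST2, the difference the design names, would remove the response to IL-33 and not that to IgE. The slopes of the ST2KO on the WT change, 0.0191 and 0.924, go with this. It stays a hypothesis, since the labels were not checked on Il1rl1.

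The 6 arrays of a comparison of 2 groups make 10 splits, too few for a share under 0.05. The real split gave 1249 genes for IgE in WT cells, 1246 for IL-33 in WT cells and 1326 for IgE in ST2KO cells, against at most 0 in another split, and 466 for IL-33 against IgE, against at most 1; in each, 1 of the 10 splits gave as many. For ST2KO against WT unstimulated cells 2 of 10 splits gave as many as the real 1, the highest other being 1, and for IL-33 in ST2KO cells all 10 gave 0. In the genotype comparison that other split parted only 1 replicate pair. Splits that parted as many pairs as the real one gave 0 there. For the IgE interaction the real count was 0, and another of the assignments gave up to 12. A count of 0 is met by all 10 splits and all 100 assignments whatever the data, so these decide nothing about chance.

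Probes outside the gene table were not part of the comparisons. Of 2870 tested, 202 passed for IgE in WT cells, 209 for IL-33 in WT cells, 81 for IL-33 against IgE, 232 for IgE in ST2KO cells and 2 between unstimulated genotypes. Groups of 3 arrays were not tested for single outlying arrays.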

How the results depend on the processing

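The settings without the 6 arrays numbered 3, and the replicate block for gene lists, were chosen only after the results were seen. No named gene reversed under any setting, and of 261 calls of named genes 254 were kept without background correction, 219 with median scaling, 257 with the authors' values, 228 without a detection filter, 204 with only the groups compared and 261 with the replicate block. Leaving out 1 array kept 1349 of 1740 calls. Under no background correction, median scaling, the authors' values and no detection filter, the 3 correlations between responses moved by less than their jackknife SE; other settings were not applied to them.

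Counts of genes moved over 1.5 times as follows, and the cause was not tested unless stated. With the replicate block, which removes the difference between numbers, they were 3426 for IgE in WT cells, 3315 for IL-33 in WT cells, 1667 for IL-33 against IgE, 3558 for IgE in ST2KO cells, 21 for genotype and 1639 for the IL-33 interaction. Without the 6 arrays numbered 3 the counts were 3912, 4069, 2199, 3880, 533 and 2563 in this order, and 15 for the IgE interaction; with the block as well 4148, 4288, 2457, 4114, 607, 2836 and 27. IL-33 in ST2KO cells gave 0 in limma under each of these. With only the groups compared, where fewer arrays estimate the spread, they were 755 for IL-33 in WT cells, 294 for IL-33 against IgE, 483 for IgE in ST2KO cells, 0 for genotype and 141 for the IL-33 interaction. For genotype, no background correction and median scaling each gave 2 genes. With no detection filter, where 19057 genes were tested, the IL-33 interaction gave 145.

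Leaving out 1 array gave 594 to 1243 genes for IgE in WT cells, 624 to 1727 for IL-33 in WT cells, 224 to 486 for IL-33 against IgE, 658 to 1600 for IgE in ST2KO cells, 0 to 0 for IL-33 in ST2KO cells, 0 to 6 for genotype, 0 to 0 for the IgE interaction and 99 to 577 for the IL-33 interaction. The arrays that moved the counts most are named above. These fits had no block, so leaving out 1 array unbalances the replicate numbers between groups. Lost calls can partly reflect this, which was not tested. With the block on all arrays the 261 named calls were all kept. Over the comparisons 32 lists were shifted by camera, 47 with the replicate block, 5 with an estimated correlation, 0 with both and 65 without the 6 arrays numbered 3; of the 32, 31 kept the sign of their median under the 3 scalings, the exception being the apoptosis regulators in the IL-33 interaction. The median of 18 moved by over 1.5 times, 16 of them without background correction, 5 with median scaling and 1 in the authors' values. With the arrays numbered 3 left out, camera with an estimated correlation shifted lists in the IL-33 comparisons of WT cells and in the IL-33 interaction only. For IL-33 in WT cells these were the NF-kB, cytokine, TNF superfamily and ribosome biogenesis lists. Against IgE they were the NF-kB and interferon lists. In the IL-33 interaction they were all of these and the chemokine and immediate-early lists. A block for slides was not run, as the files name no slides. Signal over background limits the dim genes.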

Other observations

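The test of the chromosome without Rpe, and the spreads and detected members set beside the replicate-3 values, were chosen only after the results were seen. On array 3 the genes furthest above arrays 1 and 2 were, as the mean log2 difference over the 6 groups, Smpdl3a (5.90), Pga5 (5.68), the mast cell chymase gene Mcpt4 (5.66), Csn1s1 (4.90), the granule protease gene Ctsg (4.83), the chymase gene Cma2 (4.75), and Cd74 (4.72) and H2-Aa (4.47) of class II antigen presentation. Embryonic globin Hbb-y (-5.25), Serpinb2 (-4.43) and the protease gene Prss34 (-3.68) were lower. Other mast cell protease genes lay close to arrays 1 and 2, with Cma1 at -0.02, Tpsb2 at -0.31 and Cpa3 at 0.02. As lists, mast cell proteases had a median of 0.74 over the groups (2.84 in WT and -0.04 in ST2KO unstimulated cells), eosinophil markers of 1.87, basophil markers of 0.71, neutrophil and progenitor granule genes of 0.64, macrophage and dendritic cell markers of 0.46 and interferon-response genes of 0.46. These genes were chosen after their values were seen, and no theme among them was tested.

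A weaker signal on the replicate-3 arrays could set them apart. On complete arrays their mean intensity was 288.8 to 331.8, against 353.1 to 388.5 for replicates 1 and 2. Their median was 86.4 to 89.1 against 92.5 to 97.9, but the median probe was undetected, so the median reflects background. The share of probes detected was alike, at 35.4% to 38.6% against 35.1% to 37.2%. Of the 2633 brightest genes 5.39% ± 0.44% (binomial SE) were over 2-fold from the mean of arrays 1 and 2 in unstimulated WT cells and 10.5% ± 0.60% in ST2KO cells, against 0 between arrays 1 and 2; the bound of 5% in both groups was passed by less than the spread in WT cells, so this stays open. All other cell types rising together in the cultures are argued against: the erythroid and megakaryocyte list, relative to all genes, stood at -0.67 ± 0.45 in WT and -0.34 ± 0.22 (bootstrap SE) in ST2KO unstimulated cells, and its 6 members detected there at -1.02 ± 0.46 and -0.59 ± 0.28. A rise of some cell types stays open, as the detected members lay above all genes in the 4 other lists: macrophage and dendritic cell (7 genes, 1.64 ± 1.0 and 0.54 ± 0.67), neutrophil (2 genes, 3.26 ± 2.1 and 2.89 ± 0.97), eosinophil (2 genes, 1.82 ± 0.23 and 2.47 ± 0.74) and lymphocyte markers (2 genes, 1.82 ± 1.3 and 2.11 ± 1.8). Over all measured members these 4 lists stood lower or the same in most cases. In WT and ST2KO cells the values were 0.84 and 0.49 for macrophage and dendritic cell (13 genes) and 0.44 and 1.46 for neutrophil markers (5). They were 1.82 and 2.47 for eosinophil (2) and 0.11 and -0.15 for lymphocyte markers (4). Detection was counted over the same unstimulated arrays, so a rise on array 3 can itself favour a member. The maturity of the cultures or a separate preparation was not tested, since the labels name no batch.

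With the replicate number shared by both genotypes as a block, 21 genes differed between unstimulated ST2KO and WT cells. Besides Rpe (-2.38 ± 0.24 SE, n = 3), Sort1 (-1.93 ± 0.27), 3110040M04Rik (-1.58 ± 0.23), Amph (-1.57 ± 0.26), Prss34 (-1.36 ± 0.22) and Ogfrl1 (-1.23 ± 0.23) were among the lower genes, and Man1a (2.19 ± 0.33), Arhgef4 (1.19 ± 0.17) and Gfi1, a transcription factor gene (0.89 ± 0.14), among the higher. Chromosome flanking the targeted locus, carried along from another strain, is a candidate explanation for some: 4 of the 20 genes with a known chromosome, Rpe, 3110040M04Rik, Ogfrl1 and Arhgef4, lie on that of Il1rl1, against 1.08 expected from the 5.38% of all genes tested there (1-sided Fisher exact p = 0.0202). Rpe had been seen before and prompted the test; without it 3 of 19 genes lay there, against 1.02 expected (1-sided Fisher exact p = 0.0789). This explanation therefore stays open, and the strain in which the knockout was made was not analysed here.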
